A study of Mus musculus with 8 samples.

How the data were processed

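RNA sequencing was done on 8 samples of mouse neural stem cells from the subventricular zone, cultured with EGF and FGF-2 and nucleofected, 4 labelled control and 4 labelled shPaupar. Per the labels' protocols, total RNA was treated with DNase, ribosomal RNA was removed with probes, and libraries primed with random hexamers were sequenced as paired reads. Removal of ribosomal RNA, without selection of poly(A) tails, keeps unspliced and non-polyadenylated RNA, so retained introns and non-coding RNA enter the measurements. The submitters' processing notes name CASAVA, HISAT2, HISAT, TopHat2 and StringTie, without roles or versions. The counter, the statistical test, the use of strand and the genome build are not given in the sources used here.

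The data used were a single comparison table made by the authors, with 156 rows. The authors' deposited group levels are a signal on a scale whose normalization is not stated, with 1 value for knockdown and 1 for control. The deposited fold change is on the log2 scale, knockdown over control, and its sign equals the sign of the level difference in 156 rows. The deposited p-values come unadjusted and adjusted for multiple tests, by a method the file does not name. Groups listed below 1e-10 (in the file about 1e-17) were treated as listed at 0. The last row was shifted by 1 column and was read accordingly, and a row that repeats another was counted once, leaving 155 features.

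A test between samples had been planned for a table with values per sample. The table gives 1 value per group, so no such test was run, and the authors' fold changes and adjusted p-values are described in its place at a threshold of 0.05, which all 155 features pass. No depth, standard deviation or interval can be given from these values.

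Adjusted p-values were checked against the Benjamini-Hochberg rule, in which an adjusted p equals the p-value times the number of tests divided by the rank. The rows were placed in 2 sets, for which this rule gave 29506 and 89072 tests. The GENCODE M21 annotation (assembly GRCm38) has 55536 genes and 141862 transcripts. Rows were assigned to a set by this rule and by the order of their p-values, which was kept in 156 rows within their own set, while 128 rows were out of order in the other set. The assignment of 14 rows rests on the order alone. The names gene-level and transcript-level describe what the loci match, since no column of the file names the sets. Loci of 110 of the 123 gene-level features equal gene spans of the annotation, whereas those of 19 of the 32 transcript-level features equal retained-intron transcripts of protein-coding genes. These matches are largely fixed by the assignment, which used the loci. Coordinates are as listed in the file, and those of Paupar and Pax6 are from the annotation. The largest rank was 142 in the gene-level set and 550 in the transcript-level set, so 19 and 518 ranks are not among the rows used here. The search for the totals was tested on 20 simulated tables and recovered both in 20, the first within 5 tests and the second exactly. Rows of the 2 sets were already apart there, so the assignment of rows was not tested. In the data, a whole rank fitted 88 of the 112 rows that gave the first total and 7 of the 8 that gave the second.

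Standard errors were derived as the log2 fold change divided by the normal quantile of the two-sided p-value, on the assumption of a Wald test. Gene lists, 18 in number, and the rule for named genes were fixed before the data were examined. The rule took Paupar, Pax6 and Trim28, the 12 largest increases and 12 largest decreases among features with a level of at least 1 in a group, without unnamed loci, predicted genes (Gm and Rik symbols) or pseudogenes, and up to 4 members of each list by smallest adjusted p. Lists with at least 5 members in the table were tested for direction against the other features with Fisher's exact test, two-sided. Such a test describes a table selected for change and treats genes as independent. Alternatives were a threshold of 0.01, an absolute log2 fold change of at least 1, pseudocounts of 0.1 and 1 on the group levels, and 4 choices made after the data were seen. Calculations used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1.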

Results

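Gene expression was measured by RNA sequencing in neural stem cells grown from the mouse subventricular zone (SVZ), the germinal niche that lines the lateral ventricles of the brain. Paupar, a long non-coding RNA transcribed beside the transcription factor gene Pax6, was targeted with a short hairpin RNA (shPaupar). The series has 8 samples, 4 labelled shPaupar and 4 labelled control, and what the control cells received is not stated in the labels. The single comparison asks which transcripts differ between Paupar knockdown and control cells, in a study whose title also names the chromatin regulator KAP1 (gene symbol Trim28). The authors' deposited table has 156 rows and gives 1 level per group, a log2 fold change (shPaupar over control), a p-value and an adjusted p for each. Values per sample were not analysed here, so the levels carry no replicate error and the depth per sample is unknown. Whether a difference exceeds the spread between samples therefore rests on the p-values in the authors' deposited table. The test behind these p-values is not given, so it is not known whether they measure the spread between the 4 samples of a group. The labels do not say that the samples of a group came from separate animals or cultures, so that spread may be technical.

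More features were lower than higher after Paupar knockdown. In the authors' deposited table, 1 row repeats another, and of the 155 distinct features 54 were higher and 101 lower in shPaupar cells (65.2% lower). Their adjusted p-values run from 7.86e-12 to 0.0471 in the authors' deposited table, so it is a list already selected for change and not a count over all genes tested. The rows were placed in 2 sets, whose adjusted p-values imply 29506 and 89072 tests. Rows of the first mostly match whole genes and those of the second non-coding transcripts. These matches are largely fixed in advance, since loci were used to assign the rows and only non-coding transcripts were searched. The gene-level set held 123 features in the authors' deposited table, 33 higher and 90 lower (73.2% lower), while the transcript-level set held 32, of which 21 were higher and 11 lower. The 2 splits were not tested against each other, because the rows of the authors' deposited table cover 86.6% of the ranks implied for the gene-level set but 5.8% for the transcript-level set. Of the features with an absolute log2 fold change of at least 1 in the authors' deposited table, 32 were higher and 36 lower when both sets are pooled. The 36 gene-level ones split into 11 higher and 25 lower (69.4% lower), against 22 and 65 (74.7% lower) among the gene-level features under 1 in the authors' deposited table, and the rest are the transcript-level features.

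Changes of whole genes were mostly modest. The 112 gene-level features above 0 in both groups had a median absolute log2 fold change of 0.59 (1.51-fold) in the authors' deposited table, and 87 of all 123 lay under 1. Among the 98 gene-level features with a level of at least 100 in a group and above 0 in both, 27 were higher and 71 lower, with a median of 0.54 (1.45-fold) in the authors' deposited table. If the p-values in the authors' deposited table came from a two-sided normal (Wald) test, which is an assumption, the median standard error of the log2 fold change was 0.126 over the 112 gene-level features above 0 in both groups.

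The following genes were chosen after their values were seen, as those with the smallest adjusted p among the gene-level features apart from a pseudogene. The smallest adjusted p was that of Anp32b, which encodes an acidic nuclear phosphoprotein (chromosome 4, 46450902 to 46472657), at a level of 16105 in shPaupar against 9605 in control cells (log2 fold change 0.75, adjusted p 7.86e-12 in the authors' deposited table). The zinc finger gene Zfp12 rose from 604 to 1882 (1.64, adjusted p 1.24e-05 in the authors' deposited table). The strongest evidence for a decrease was at Ripor2, which fell from 507 to 227 (-1.16, adjusted p 3.49e-10 in the authors' deposited table). Dio2, the deiodinase that activates thyroid hormone, fell from 4029 to 2601 (-0.63), and the secreted protease gene Htra1 had a log2 fold change of -0.60 in the authors' deposited table. Glutaredoxin 2 (Glrx2, -0.86), the cytokine gene Il33 (-0.73) and the tyrosine kinase gene Abl1 (-1.13) were also lower in shPaupar cells in the authors' deposited table, with adjusted p of 7.07e-07, 2.14e-05 and 3.26e-05. The serine protease gene Prss35 (-0.68) had the same adjusted p as Abl1 in the authors' deposited table.

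Some further genes were also picked out after their values were seen and stand for no group. Sonic hedgehog (Shh) fell from a level of 27.7 to 4.48 (log2 fold change -2.59, adjusted p 0.00497 in the authors' deposited table), both low levels. Fibroblast growth factor 1 (Fgf1, -0.41) and the chemokine gene Cxcl14 (-0.73) were lower at much higher levels, 8263 and 865 in control cells in the authors' deposited table. The endotoxin receptor gene Tlr4 rose from 79.1 to 349 (2.14, adjusted p 0.000564 in the authors' deposited table).

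Of the 18 gene lists fixed before the data were examined, which hold 404 distinct genes, 14 genes were among the rows of the authors' deposited table. Interferon and innate immune genes stood out by direction. Of the 40 members of that list, 6 were in the authors' deposited table and all 6 were higher in shPaupar cells, against 48 higher and 101 lower among the other features (Fisher's exact test, two-sided, p = 0.00148). Within the gene-level features alone, the other features of the authors' deposited table split into 27 higher and 90 lower (Fisher's exact test, two-sided, p = 0.000261). With a threshold of 0.01 on the adjusted p of the authors' deposited table, only 3 of the 6 were left, and with an absolute log2 fold change of at least 1 there were 0, both below the 5 members that the list test needs, so it could not be made there. The antiviral 2'-5' oligoadenylate synthetase genes Oasl2 (log2 fold change 0.48, adjusted p 0.000442) and Oas1a (0.75, adjusted p 0.00123) led the list in the authors' deposited table, together with the tetherin gene Bst2 (0.50, adjusted p 0.00123). The guanylate-binding protein gene Gbp3 (0.35), Ifi44 (0.46) and the antiviral GTPase gene Mx2 (0.62) followed in the authors' deposited table, with adjusted p of 0.0383, 0.0393 and 0.0426. The annotation used here gives Mx2 as a polymorphic pseudogene. Oas1a, Oasl2, Gbp3 and Mx2 belong to multigene families whose reads the authors' counting could divide, so their single values are uncertain. None of the 20 microglia and macrophage genes was among the rows of the authors' deposited table.

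Of the 30 neural stem cell and astroglial genes, 4 were in the authors' deposited table and all 4 were lower, too few for the list test, which needed 5. The amino acid transporter gene Slc7a10 fell from 127 to 61.4 (log2 fold change -1.05, adjusted p 0.00358 in the authors' deposited table). The water channel gene Aqp4 (-0.45), the glycolytic enzyme gene Aldoc (-0.43) and the glial glutamate transporter gene Slc1a2 (-0.35) were lower with adjusted p of 0.00382, 0.00802 and 0.0435 in the authors' deposited table. The locus listed for Aqp4 differs from the annotated gene span, so its values need not hold for the whole gene. Slc1a2 was abundant, at 39308 in shPaupar and 50039 in control cells in the authors' deposited table.

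Of the 30 neuroblast and neuronal genes, doublecortin (Dcx), a microtubule-associated protein of migrating neuroblasts, was the 1 member present and fell from 286 to 152 (-0.91, adjusted p 0.000777 in the authors' deposited table). The imprinted and KAP1-controlled genes, 30 in all, had 2 members in the authors' deposited table, with opposite directions. The growth factor gene Igf2 fell from 35.6 to 4.73 (-2.87, adjusted p 0.00175) and the growth factor receptor-bound adaptor gene Grb10 rose from 3781 to 4963 (0.39, adjusted p 0.00690) in the authors' deposited table. The immediate early gene Fosb fell from 280 to 183 (-0.61, adjusted p 0.0435 in the authors' deposited table), the 1 member of 24 immediate early and stress genes present.

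The other 13 lists had 0 members among the rows of the authors' deposited table. They cover activated stem cells and transit-amplifying progenitors (20 genes), the cell cycle (34), p53 and apoptosis (21), the Notch, BMP, Shh and Wnt pathways (38), cholesterol synthesis (20) and mitochondrially encoded genes (15). They also cover oligodendrocyte lineage (20), ependymal (14), microglia and macrophage (20), endothelial (12), mural, fibroblast and extracellular matrix (26), and choroid plexus and blood genes (9), and the Pax6 locus with Paupar partner genes (15). The lists are not complete for their pathways. Shh, the BMP antagonist gene Chrdl1 (-0.50, adjusted p 0.000704) and a transcript of the Wnt effector gene Ctnnb1 are rows of the authors' deposited table but not members of the pathway list, and the oligodendrocyte myelin glycoprotein gene Omg (-0.76, adjusted p 0.0243) is not on the oligodendrocyte list. Fold changes of members not among the rows used here are unknown, so a count of 0 does not show that a list was unchanged. For the same reason no count adjusted over the list alone could be given.

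**Figure D1:**
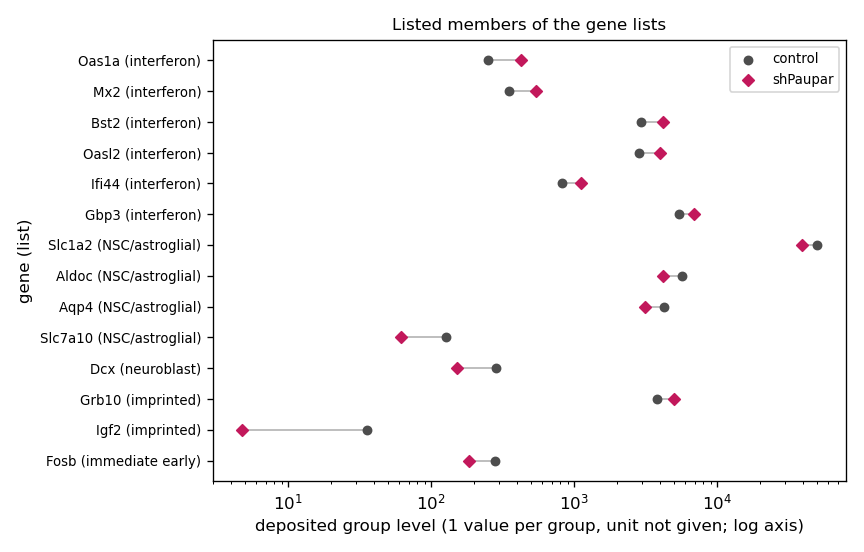
Level in control (grey circles) and shPaupar cells (pink diamonds) of the 14 genes of the fixed lists, on a log axis, as given in the authors' deposited table with 1 value per group, no error bars and no unit. The 6 interferon genes all lie higher in shPaupar cells and the 4 neural stem cell and astroglial genes all lie lower.

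Paupar, Pax6 and Trim28 were not among the rows used here, with 0 rows each, so the knockdown itself could not be checked from the authors' deposited table. Paupar lies on chromosome 2 from 105657862 to 105661343 and Pax6 from 105668900 to 105697364 in the GENCODE M21 annotation of the mouse genome. Of the 7 features on chromosome 2 in the authors' deposited table, Slc1a2 was the nearest, 2.87 Mb from Paupar, and the 1 feature within 5 Mb.

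The transcript-level features showed larger fold changes. The 20 of them above 0 in both groups had absolute log2 fold changes of at least 2.51, with a median of 4.49 (22.4-fold), in the authors' deposited table. The other 12 were listed at 0 in a group. The loci of 19 of them equal retained-intron transcripts of protein-coding genes, which keep an intron and are annotated as non-coding, and 10 belong to genes annotated as non-coding. The remaining 3 matched no annotated non-coding transcript, and protein-coding transcripts were not searched. They are Igsf9, which has no locus, XLOC_050829, which has no annotated gene, and Gkap1. A value of such a row need not hold for the whole gene. The loci of 4 rows, Relb, Arf4os, 6330403L08Rik and Gm39469, also equal the span of the whole gene, so the locus does not tell transcript from gene there. Of the protein-coding host genes, 0 of the 21 were also among the gene-level features of the authors' deposited table.

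A retained-intron transcript of Ctnnb1, the gene of the Wnt effector beta-catenin, had the highest level of the retained-intron transcripts. Ctnnb1-215 (chromosome 9, 120959216 to 120960507) was at 2513 in shPaupar and 108 in control cells (log2 fold change 4.54, adjusted p 0.0290 in the authors' deposited table). Tet2-209, from the gene of a DNA demethylating enzyme (chromosome 3, 133463683 to 133474819), was at 1032 against 59.5 (4.11, adjusted p 0.00122 in the authors' deposited table). Tecpr1-209 was at a level between these and went the other way, at 144 in shPaupar and 1083 in control cells (-2.91, adjusted p 0.0214 in the authors' deposited table). The smallest adjusted p-values of this set, other than that of Pan2, were at the antisense genes Gm9934 (594 against 7.37, 6.32, adjusted p 4.98e-10) and 6330403L08Rik (537 against 0.962, 8.95, adjusted p 3.14e-06) in the authors' deposited table. These features were named after their values were seen, and the antisense genes are uncertain without strand.

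By the rule fixed beforehand, which leaves out unnamed loci, predicted genes with Gm or Rik symbols and pseudogenes, the 12 largest increases included 9 transcript-level features and the 12 largest decreases included 7. Pan2-207, from a poly(A) ribonuclease gene (chromosome 10, 128303376 to 128307408), was at 249 in shPaupar and 5.59 in control cells (5.44, adjusted p 3.72e-09 in the authors' deposited table). Retained-intron transcripts of Acbd5 (5.41), Malt1 (5.02) and Ccdc28b (4.59) were higher at lower levels, 45.9, 40.6 and 26.0 in shPaupar cells in the authors' deposited table. Transcripts of Lrrc9, Matk and Krtcap3 were listed at 0 in control cells and at 54.2, 27.6 and 16.3 in shPaupar cells in the authors' deposited table. The same held in the authors' deposited table for non-coding Zfp469-201 (38.7) and the antisense gene Arf4os (11.0), whose reads cannot be told apart from those of its sense partner without strand.

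Among the decreases, Itpr1-209, a retained-intron transcript of an inositol trisphosphate receptor gene (chromosome 6, 108252958 to 108393000), was at 0.520 in shPaupar and 351 in control cells (-9.08, adjusted p 0.000140 in the authors' deposited table). Those of Cog7 (-5.78), Prpf40b (-3.61) and the NF-kappaB regulator gene Tnfaip3 (-3.10) were lower as well, from 121, 39.3 and 84.1 in control cells in the authors' deposited table. Transcripts of the NF-kappaB subunit gene Relb and the kainate receptor gene Grik1 were listed at 0 in shPaupar cells and at 46.4 and 29.0 in control cells in the authors' deposited table. The locus listed as Gkap1 fell from 72.7 to 0.514 (-6.82, adjusted p 0.00416 in the authors' deposited table).

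The named gene-level features with the largest changes were mostly listed at 0 in a group. The autophagy gene Epg5, at 289 in shPaupar cells, was listed at 0 in control cells, as were Ncmap (7.64) and Izumo1 (4.73) in the authors' deposited table. The locus listed for Epg5 differs from the annotated gene span, so its values need not hold for the whole gene. The same is true of 13 gene-level features in all, among them Aqp4, Fgf1 and Ccdc152. Rows of these 3 genes were not assigned to the gene-level set by their loci. Selp (8.14), Gnb3 (6.27) and Spag6 (5.33) were listed at 0 in shPaupar cells and had these levels in control cells in the authors' deposited table. Wfdc1 was above 0 in both groups and fell from 13.1 to 1.05 (-3.50, adjusted p 0.000120 in the authors' deposited table). In all, 23 features were listed at 0 in 1 group of the authors' deposited table, 11 in shPaupar and 12 in control cells, and their folds are not printed here because they depend on how a level of 0 was treated. Their deposited log2 fold changes entered only counts, ranks, the standard errors of the transcript-level set and the plot of fold change against level.

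**Figure D2:**
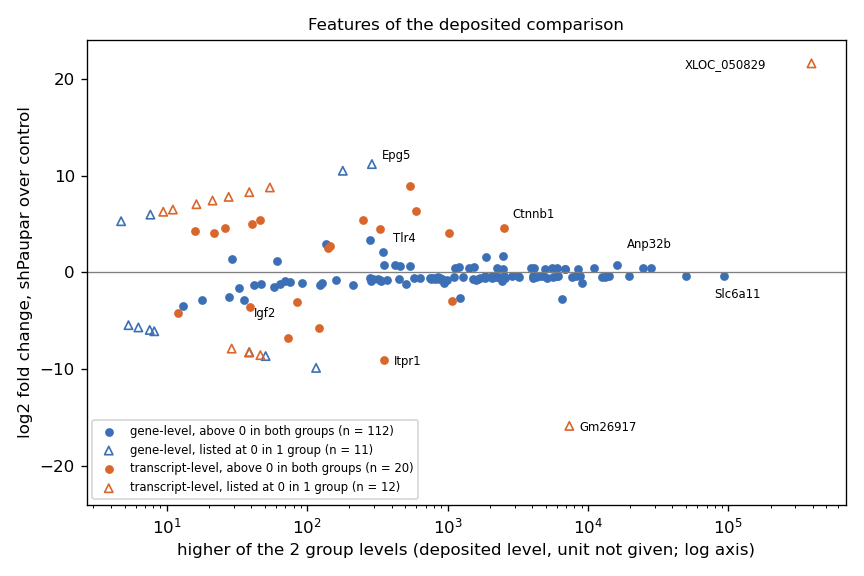
Log2 fold change (shPaupar over control) against the higher of the 2 group levels (log axis, no unit given) for the 155 distinct features of the authors' deposited table. Filled circles are above 0 in both groups and open triangles are listed at 0 in 1 group, with gene-level features in blue (123) and transcript-level features in orange (32). Most gene-level features lie close to 0 and every transcript-level feature lies at least 2.51 away from it on the deposited scale.

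Some rows name a gene that their own identifier or locus contradicts. The row named e2f7, listed at 0 in shPaupar and 50.6 in control cells in the authors' deposited table, carries the locus (chromosome 16, 20611601 to 20645920) and description of an Eef1akmt4-Ece2 readthrough gene, whereas E2f7 lies on chromosome 10. The row named Nek4 repeats the locus and values of Gkap1 on chromosome 13 in the authors' deposited table, although Nek4 lies on chromosome 14. The row named Spag6 carries the identifier and description of its paralog Spag6l, and the row named Adat3 those of the predicted gene Gm49322, which overlaps Adat3 on chromosome 10. The row named Igsf9 gives no locus and its values are shifted by 1 column in the authors' deposited table. Selenop and Ccdc152, both lower, overlap by 9641 bases on opposite strands, as do Kcnip1 and Kcnmb1 by 10629 bases in the loci of the authors' deposited table. The genes Gabrb1 and Gabra4, both lower, share 196 bases in the authors' deposited table. The use of strand in counting is not given in the sources used here, so the values of the genes in these pairs are uncertain.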

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

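The alternatives restricted to gene-level features, to features above 0 in both groups, and to rows without a contradicted name or locus (with and without Adat3 and Spag6) were chosen after the data were seen. Of 40 alternative counts, 30 stayed within 1.5 times the main count and 10 did not, and lower features stayed more numerous than higher ones. Much of this stability was fixed in advance. All 14 list genes were gene-level, above 0 in both groups and without a contradicted name or locus. The alternatives chosen after the data were seen could therefore move no list count. With a threshold of 0.01 on the adjusted p of the authors' deposited table, 29 features were higher in place of 54 and 65 lower in place of 101, 9 list genes were left of 14, and 3 interferon genes of 6. With an absolute log2 fold change of at least 1 as well, the authors' deposited table gave 32 higher and 36 lower features, 2 list genes, 0 interferon genes and 1 neural stem cell and astroglial gene of 4, since most gene-level changes are smaller than that. Gene-level features alone gave 33 higher in the authors' deposited table, since 21 of the higher features are transcript-level. Pseudocounts of 0.1 and 1 moved no count, which the use of signs alone fixes. No paired analysis was possible because the table gives 1 value per group and the replicate numbers of the samples have no columns in it. Other normalizations, a filter on low values, other tests, a replicate block and leaving out each of the 8 samples were planned and not run, for the same lack of values per sample. Which changes rest on a single sample, and what depth limits, is therefore open.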

Other observations

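All tests in this part were chosen after the results were seen. Besides the fixed list, 5 further interferon-stimulated genes, picked after their values were seen, were higher in shPaupar cells in the authors' deposited table: Trim30a (log2 fold change 0.54), Gm4951 (0.72), Lgals9 (0.54), Parp9 (0.43) and Rnf213 (0.45). A set picked in this way cannot serve as a test of its own direction. Rnf213, an interferon-inducible ubiquitin ligase gene, was the most abundant of them, at 28054 in shPaupar and 20532 in control cells in the authors' deposited table.

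A class of genes was formed after the values were seen from the words receptor, channel or solute carrier in their descriptions. It holds the nuclear receptor gene Rora but not the water channel gene Aqp4. Not every gene with these words was kept. Grb10 (log2 fold change 0.39), Lrp11 (-1.05), Kcnip1 (-0.59) and Kcnip3 (-0.41) were left out and counted among the other gene-level features. Of the 18 gene-level features kept in the class, 16 were lower in the authors' deposited table. They included the GABA receptor subunit genes Gabrb1 (-0.70) and Gabra4 (-0.40) and the glutamate receptor genes Gria1 (-0.54) and Grm3 (-0.34). The adenosine receptor gene Adora2a (-0.91) and the GABA transporter gene Slc6a11 (-0.39) were among them too. The 2 higher ones were Tlr4 (2.14) and Kcnmb1 (1.36) in the authors' deposited table. The hypothesis that this class fell more often than others did not pass its test, with 88.9% lower against 70.5% of the other 105 gene-level features (Fisher's exact test, two-sided, p = 0.15). The excess of lower features in the whole authors' deposited table remains a candidate explanation.

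Higher interferon genes are one pattern for a closer look. Chance membership of the list is argued against by an exact one-sided hypergeometric test, in which 6 of 40 members among 123 listed of 29506 tested genes gave p = 1.59e-08, and p = 8.35e-06 if only 10000 genes could have been called. That test treats genes as independent, although interferon genes rise together. A larger share of microglia or macrophages could raise them. The rows used here cover 86.6% of the ranks implied for the gene-level set and hold 0 of 20 markers of these cells. Markers that changed without passing the threshold cannot be seen, so this stays open. A response to introduced RNA or to nucleofection may also differ between the groups, and cannot be told apart from an effect of Paupar loss. The labels do not say what the control cells received, and shPaupar is the only knockdown group. They also name 0 groups said to lack an introduced hairpin.

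Large fold changes of the transcript-level features are another. Low levels stay open: 13 of the 32 reach a level of at least 100 in a group in the authors' deposited table, but every feature of this set passes an absolute log2 fold change of 2, so no comparison with gene-level features at matched levels could come out otherwise. A change of the whole host gene that passed the threshold would place the host in the gene-level set. The rows used here cover 86.6% of the ranks implied for that set, and 0 of the 21 protein-coding hosts were among them. Hosts could still lie in the 19 ranks without a row, beyond the largest rank or below the threshold, so this is not excluded. Selection of rows by fold could also produce the pattern, since 518 of the 550 ranks implied by the adjusted p-values of the authors' deposited table are not among the rows used here. Under the Wald assumption, the standard errors of the 32 features were at least 0.69, with a median of 1.27. That median includes the 12 features listed at 0 in a group. These standard errors were derived from the same folds and p-values, so they are not separate evidence. If they hold, rows this imprecise pass the threshold on the adjusted p only with large folds. Selection by adjusted p could then produce the pattern as well. A difference in splicing after Paupar loss remains a hypothesis that these values do not test.

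The highest level in the authors' deposited table, 391153 in shPaupar cells, belonged to the assembled locus XLOC_050829 on a CAST/EiJ strain scaffold of chromosome 11. This locus was listed at 0 in control cells (adjusted p 0.0117 in the authors' deposited table). The lncRNA gene Gm26917 (chromosome 17, 39845074 to 39846245) was listed at 0 in shPaupar and 7368 in control cells (adjusted p 0.00282 in the authors' deposited table). Rn18s-rs5, a pseudogene related to 18S ribosomal RNA, starts after 108 further bases in the RefSeq annotation of GRCm38. Under the Wald assumption, the standard errors of XLOC_050829 and Gm26917 were 5.19 and 3.44, against a median of 1.27 in the transcript-level set.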
